A study of Sus scrofa with 14 samples.

How the data were processed

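The data cover 14 samples of embryonic pig brain, each the only library of its group: forebrain at embryonic day (E) 23, cortex at E42, E60, E80, E100 and E115, and basal ganglia, brain stem, cerebellum and hippocampus at E60 and E115. Per the labels' protocols, total RNA over 200 nt was depleted of ribosomal RNA with Ribo-Zero and libraries were made with ScriptSeq v2. The labels do not say whether libraries came from separate animals, and p-values here measure the spread between regions or around a line over stages, not between animals. Groups were taken from the sample labels and columns were matched to samples by their headings. The number of value columns without a sample was 0.

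Reads over backsplice junctions were deposited as whole counts per library in a table of forebrain and cortex and a table of 5 regions, per the file headers. Their RPM values (reads per M library reads) were computed by the authors, per the file headers, and are listed at 0 where a circRNA has 1 read. FPKM values of host genes were deposited beside them, per the file headers, and the submitters' processing notes name Cufflinks and Cuffdiff. Other values, the number of unique junction reads and the genomic length between the junction ends, were deposited per the file headers. Those notes also name Trim Galore, TopHat2 and the build Sscrofa10.2 (susScr3), without versions. The circRNA caller and its filters are not given in the sources used here. The deposited tables have at least 2 unique reads in every line and genomic lengths from 100 to 99744 bp, with a median of 9662 bp in the cortex table and 9622 bp in the regions table. Positions are given on that build, counted from 1. Whether junction ends lie in exons, introns or untranslated regions was not examined, since no annotation of that build was used here.

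Each line states the reads of all its libraries together. In 588 of 5585 lines of the cortex table and 191 of 3967 lines of the regions table the library reads did not add up to that total, and in 26 lines of the cortex table they exceeded it. Those lines held 0.808% to 10.9% of a library's reads in the cortex table and 0% to 35.9% in the regions table (35.9% in the E60 brain stem, 23.2% in the E115 hippocampus). The lowest were the E100 cortex and the E115 basal ganglia. They had 0 reads in 95.2% and 100% of those lines, against 54.2% and 85.9% of the lines that added up. Every other library had 0 reads less often in those lines. Reads of the E100 cortex and E115 basal ganglia may thus be missing there, so neither dropping nor keeping the lines is neutral for them. Of 2832 circRNAs in both tables, the E60 and E115 cortex reads differed in 0 of 2341 that added up in both and in 365 of the other 491. Only lines that added up were used, 4997 and 3776. This filter was chosen after the files and exploratory fits on all lines had been seen, and all lines were used as an alternative.

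Library totals of 9.67 to 58.8 M reads were recovered as reads divided by RPM. What reads these totals count is not stated in the sources used here. Levels are circRNA reads per M of that total (RPM), with 95% exact Poisson intervals, and shares have 95% exact (Clopper-Pearson) intervals. Both cover counting error only, since reads carry no molecular identifiers. A ratio of a pair of levels has an exact conditional interval. A count of 0 allows up to 3 reads (a bound on 1 side), which is 0.0510 RPM at E23 and 0.310 in the E115 basal ganglia; the intervals on both sides that are given with levels end higher for 0 reads, at 0.0627 and 0.381 RPM. A circRNA counted as detected from 2 reads. The highest library or stage was named for circRNAs with at least 50 reads. Both tables were tested separately, and their cortex totals differ because they list different circRNAs.

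Host names are those of the tables, set by overlap. Of 744 Ensembl gene IDs among them, 280 had a symbol in the gene name table. More than 1 host name stood in 380 and 318 lines, and 206 lines of the cortex table had none.

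Counts were tested with edgeR 4.0.16 (quasi-likelihood test) in R 4.3.3 on circRNAs with at least 20 reads over the libraries of a fit, scaled by the library totals, with Benjamini-Hochberg adjustment and a threshold of 0.05. The cortex trend had a linear term in day over 6 libraries, and its log2 change is given over the span from E23 to E115. The day effect (E115 against E60) had region as a block over 10 libraries, and region terms were tested in the same fit, together and as each region against the mean of the other 4. The common dispersion was 0.997 in the regions and 0.626 in the cortex series. Totals of circRNA reads and of circRNAs detected were tested with exact sign-flip permutations over 5 regions and exact permutations of day over 6 libraries. The circular-to-linear ratio test that had been planned was not run, because the tables used here give no linear junction reads.

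Host gene lists were tested with camera in limma 3.58.1 with a preset correlation of 0.01 and with an estimated correlation, on the most abundant circRNA of each host. The 15 lists were synapse, axon guidance and neuronal migration, Wnt signalling, TGF-beta and BMP signalling, chromatin regulation, cell cycle with centrosome and mitosis, RNA binding and splicing, astrocytes and radial glia, oligodendrocyte lineage, cerebellum, basal ganglia, brain stem, cortex and hippocampus, vascular with blood, microglial, meningeal and choroid plexus cells, and conserved circRNA hosts. Lists with fewer than 3 tested hosts were described by their levels.

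The tests, the lists, most alternatives and the rule for naming circRNAs were fixed before the data were examined. The rule named, per table, the 10 circRNAs with most reads. For the trend and the day effect it named the 10 largest changes in each direction past the threshold with at least 50 reads, and for each region contrast the 3 largest. It also named the 2 to 4 members of each list with most reads, the 2 circRNAs with the highest ratio to the other stages at each cortex stage, hosts with 10 or more circRNAs, and the most abundant circRNA of RIMS2, RIMS1, HOMER1, HDAC2, CSPP1, SMARCA5, RBM33, KAT6B, MAN1A2 and other fixed hosts where listed. Some circRNAs and hosts that the rule names are not reported here.

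Alternatives were TMM factors, DESeq2 size factors, no filter beyond 1 read, at least 50 reads, the test of DESeq2 1.42.0, limma on log2(RPM + 0.5), rank or log2 of the day, all circRNAs of each host, other detection limits, each library or region left out, and all lines. The count tests were tested on simulated data with 200 changed circRNAs (seed 1). In the day effect at the fitted dispersion, on 338 circRNAs, edgeR recovered 10.5% of 4-fold, 15.6% of 8-fold and 50.8% of 16-fold changes, and at 0.1 times that dispersion, on 362, it recovered 74.2%, 98.5% and 100%. In the cortex trend, on 698 circRNAs, it recovered 1.72%, 6.15% and 24.6%, and at 0.1 times the dispersion, on 754, 60.6%, 92.5% and 100%. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.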

Results

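Circular RNAs (circRNAs) are closed RNA loops made when a splice donor is joined to an upstream acceptor, and they were counted here by the sequencing reads that cross such a backsplice junction. Total RNA depleted of ribosomal RNA was sequenced from 14 embryonic pig brain samples. They were forebrain at embryonic day 23 (E23), cortex at E42, E60, E80, E100 and E115, and basal ganglia, brain stem, cerebellum and hippocampus at E60 and E115. Each combination of region and day was 1 library with no replicate, so intervals below cover counting error only and no spread between animals could be estimated. E23 was sampled as forebrain and the later stages as cortex, so a difference of E23 from later stages may reflect tissue as well as day. A table of forebrain and cortex held 4997 circRNAs with reads that added up to their stated totals, and a table of 5 regions held 3776. The cortex series had 21.4 to 58.8 M (1e6) reads per library and 8098 to 17336 circRNA reads. The other region libraries had 9.67 to 37.7 M reads and from 518 (E60 brain stem) and 1213 (E115 basal ganglia) to 6056 circRNA reads, so low values in the smaller ones rest on few reads.

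The question of when circRNAs were most abundant in the developing cortex was addressed by the circRNA reads per M library reads (RPM). The level was highest in mid-gestation, at 643 RPM at E42 (95% exact Poisson interval 633 to 652) and 809.6 at E60 (797.6 to 822). It was 284 in the E23 forebrain (279.7 to 288), 304 at E80 (297 to 311), 271 at E100 (266 to 275) and 216 at E115 (212 to 219.98). The E60 cortex thus held 3.75 times the level of the E115 cortex (interval 3.66 to 3.84). E42 and E80 were sequenced to nearly the same depth, 26.7 and 26.6 M reads, and E42 held 2.11 times the level of E80 (2.06 to 2.17). The number of circRNAs with at least 2 reads was 2170 at E23, 2295 at E42, 2325 at E60, 1283 at E80, 1756 at E100 and 1472 at E115. Much of this followed the number of circRNA reads: with every library drawn down to 8098 of them, a calculation added after the results were seen, the expected numbers were 1215, 1267, 1291, 1283, 1200 and 1079. Of 311 circRNAs with at least 50 reads, 142 (45.7%) had their highest level at E60 and 98 (31.5%) at E42, against 26 at E23, 13 at E80, 18 at E100 and 14 at E115. The 311 were chosen by reads over all stages together, of which E60 and E42 had the most (17336 and 17157). This count thus follows in part from the totals and is no separate support for them. The level was highest in the middle of the series, and no straight relation with day was found over the 6 libraries. Spearman's rho was -0.60 (exact permutation p = 0.242, two-sided) and Pearson's r was -0.44 (exact permutation p = 0.379), with adjusted p of 0.322 and 0.379 in a family of 4 tests. Without the E23 forebrain rho was -0.90 and r was -0.85 (exact permutation p = 0.0833 and 0.0917), and without E100 or E115 rho was -0.30 (exact permutation p = 0.683) and r was -0.36 or -0.25. For the number of circRNAs detected, rho was -0.60 (exact p = 0.242) and r was -0.74 (exact p = 0.113), each with an adjusted p of 0.322. Without E23 and E115, the days farthest from the median, r was -0.81 for the level (exact permutation p = 0.208) and -0.69 for the number detected (exact p = 0.333).

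**Figure D1:**
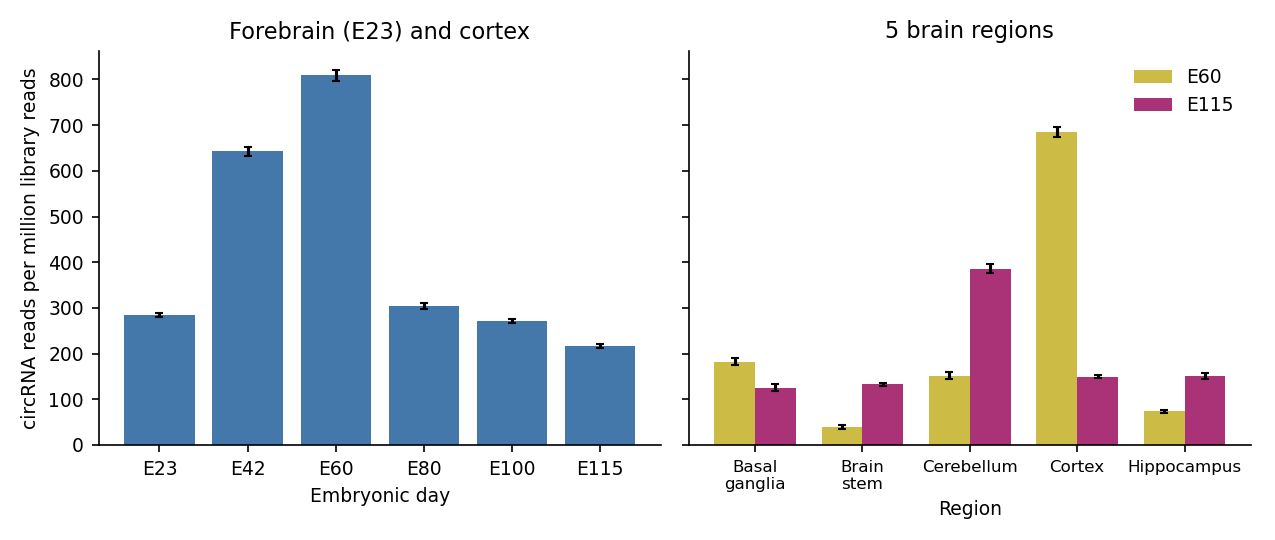
All circRNA reads together, in RPM, in each library (bars, with 95% exact Poisson intervals for counting error, 1 library each): left, the E23 forebrain and the cortex from E42 to E115; right, 5 brain regions at E60 and E115. In the left panel the E60 bar is highest at 809.6; in the right panel the E60 cortex stands at 685, and cerebellum, brain stem and hippocampus are higher at E115 than at E60. The panels come from separate tables that list different circRNAs, so their cortex bars differ.

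Individual circRNAs marked different stages of the cortex series. In the E23 forebrain the highest ratios to the other stages belonged to circRNAs from the genes ENSSSCG00000030035 (chromosome 9, 126101169–126105141; 62 reads at E23 and 1 in all later stages together) and ENSSSCG00000030096 (chromosome 6, 97024076–97096660; 3.13 RPM at E23, 7.90 times the mean of the other stages). At E42 they belonged to a circRNA of VCAN, which encodes the extracellular matrix proteoglycan versican (chromosome 2, 93851810–93857047; 5.88 RPM, 4.998 to 6.88), and to one of ZC3H6 (chromosome 3, 45698129–45716254; 2.17 RPM). A circRNA outside any listed host gene (chromosome 7, 69988389–69988716) reached 10.7 RPM at E60. At E80 the highest ratio was that of the circRNA whose host gene the table gives as CDR1 (chromosome X, 131493485–131495109), at 5.14 RPM (4.32 to 6.08), 2.41 times the mean of the others, followed by one of ENSSSCG00000025844 (chromosome 17, 14861638–14933362; 3.605 RPM). The circRNA assigned to CDR1 is listed on the plus strand of the chromosome, and its host name comes from overlap. Whether it is sense or antisense to CDR1 was not established, and it was not matched to a known antisense transcript. At E100 a circRNA without a host gene (chromosome 9, 19582066–19609249) stood at 2.88 RPM. At E115 the highest ratios belonged to circRNAs of SYN2, the synaptic vesicle protein synapsin II (chromosome 13, 75379989–75404735; 1.89 RPM, 1.54 to 2.29), and of ENSSSCG00000028457 (chromosome 7, 132158912–132159305), which had 110 reads at E115 but 0 at both E80 and E100.

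The most abundant circRNAs of the cortex series followed several courses. The circRNA with most reads, from ENSSSCG00000020975 (chromosome 13, 210806110–210875564), was at 1.94 RPM at E23, 7.77 at E80, 9.01 at E100 and 8.32 at E115 (7.56 to 9.12). One of ENSSSCG00000026340 (chromosome 6, 73334893–73430424) also had its highest values late, at 3.65 RPM at E100 and 3.76 at E115. Others were highest at E60. A circRNA of HDAC2, a histone deacetylase (chromosome 1, 89940534–89940816), had 2.36 RPM at E23, 14.5 at E60 (12.95 to 16.2) and 0.167 at E115 (0.0762 to 0.316), so that the E60 library held 87.1 times the level of the E115 library (interval 45.3 to 192). A circRNA of CSPP1, which encodes a centrosome and spindle pole protein (chromosome 4, 73740572–73750002), had 10.6 RPM at E60 and 2.56 at E115. A circRNA of RIMS2, a scaffold of the presynaptic release site (chromosome 4, 35844936–35911000), had 0.391 at E23, 10.04 at E60 and 2.96 at E115. A pair of circRNAs of the kinase gene TLK1 (chromosome 15) shared the end at 86671532. The one starting at 86639052 had 7.75 RPM at E60 and 1.78 at E115, and the one starting at 86622619 had 7.47 and 1.56. The circRNA of ENSSSCG00000014268 (chromosome 2, 139227898–139244383) had 8.41 RPM at E60. The remaining members of the 10 most abundant, from BTF3L4 (chromosome 6, 147753296–147835689) and CDK13 (chromosome 18, 59685146–59696045), were highest at E42, at 5.10 and 4.38 RPM. Less abundant circRNAs of hosts known from other mammals were those of RIMS1 (0.0170 RPM at E23 and 3.27 at E60), KAT6B (1.17 at E60), MAN1A2 (0.654 at E60), RBM33 (0.527 at E23), SMARCA5 (0.514 at E60) and HOMER1 (at most 0.187). Several of these names were known from the study of these same samples, so their presence is no independent observation.

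**Figure D2:**
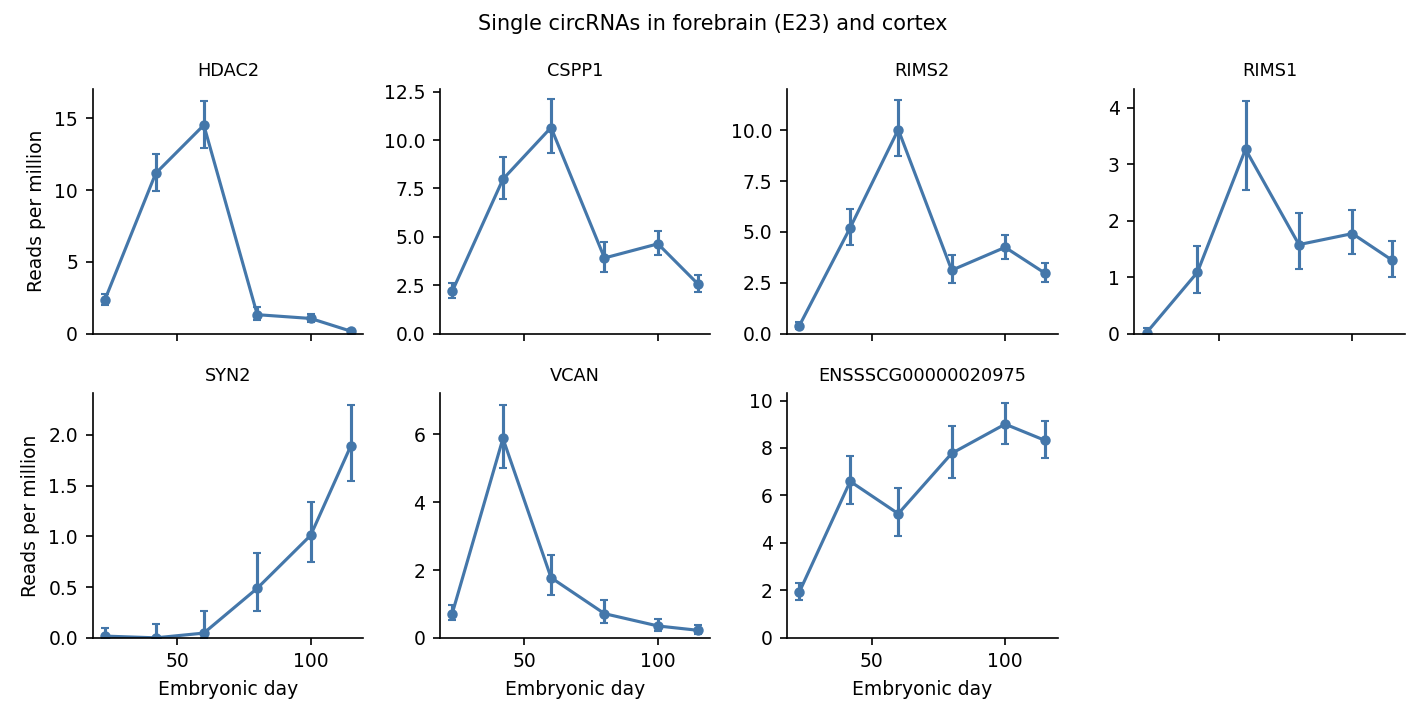
Level in RPM of 7 circRNAs, named by their host gene, against embryonic day in the E23 forebrain and the cortex (points, 1 library each, with 95% exact Poisson intervals). HDAC2, CSPP1, RIMS2 and RIMS1 are highest at E60, VCAN at E42, SYN2 at E115 (1.89) and ENSSSCG00000020975 at E100 (9.01).

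A linear change over embryonic day was tested for 803 circRNAs with at least 20 reads, with edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment. The SYN2 circRNA rose, by 7.63 on the log2 scale over the span from E23 to E115 (SE 1.43, edgeR adjusted p = 0.0145), with 1, 0, 1, 13, 49 and 102 reads at the successive stages. The circRNA of ENSSSCG00000030096 fell by 8.26 (SE 1.35, edgeR adjusted p = 0.0063; 184, 40, 5, 6, 1 and 0 reads), and that of ENSSSCG00000030035 fell by 12.19 (edgeR adjusted p = 0.0145; 62 reads at E23, 1 at E42 and 0 later, so this fitted slope has no stable size). Both falls rest mainly on the E23 library, the only one of forebrain, so day and tissue cannot be told apart for them. No other circRNA passed, and 88 had an unadjusted p under 0.05. The residual of this test is the scatter of stages around a straight line, so circRNAs that peak in the middle are not called. The count of 3 depended on the scaling. With TMM factors, which set the bulk of circRNAs level, 41 were called, 27 up and 14 down, and DESeq2's own test called 20 (5 up, 15 down), while limma called 0. Scaled by library totals the median circRNA changed by -1.47 over the span, and by -0.19 with TMM factors. Without E23, 178 were called, 172 of them down, whereas TMM factors without E23, an alternative chosen after the results were seen, called 42, 30 of them up and 12 down. The count was 26 without E60 and 0 without E42, E100 or E115.

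Host genes of synaptic proteins supplied a larger share of cortical circRNA reads at the later stages. circRNAs of 34 synapse hosts made up 0.503% of circRNA reads at E23, 1.91% at E42, 3.25% at E60, 3.33% at E80, 5.03% at E100 and 4.89% at E115, while their level was 1.43, 12.3, 26.3, 10.1, 13.6 and 10.6 RPM at these stages, highest at E60. Without RIMS2, the circRNA of the list with most reads, the share still went from 0.365% at E23 to 3.46% at E100 and 3.52% at E115; shares without such a member were computed after the values were seen. With 1 circRNA per host, 9 synapse hosts could be tested for the trend. SYN2 was called up, none was called down and 8 were not called, and 1 was called when adjusted over the list alone. 7 of the 9 slopes were above 0, and their median of 1.70 stood against -1.48 over all 581 hosts (limma's camera test with a preset correlation of 0.01, adjusted p = 3.05e-06). The slopes depend on the scaling, and with TMM factors the median was 3.48 against -0.17 over all hosts (limma's camera, adjusted p = 4.75e-06). With an estimated correlation limma's camera did not call the list (adjusted p = 0.211). Members that were not called included some with slopes of 1.70 (RIMS1, SE 1.94), 0.24 (RIMS2, SE 1.71) and -1.39 (CAMK2A, SE 1.31). The test without SYN2 was chosen after its values were seen. Without SYN2 the median was 1.48 (limma's camera, adjusted p = 0.000955 with the preset and 0.866 with an estimated correlation).

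Hosts that regulate chromatin supplied 3.76% of circRNA reads at E23, 4.74% at E42 (30.5 RPM) and 2.43% at E115 (5.24 RPM) over 48 hosts, but much of this came from the HDAC2 circRNA, with 298 of 814 reads at E42 and 9 of 283 at E115. Without it the share was 2.93% at E23, 3.01% at E42 (2.76% to 3.27%) and 2.35% at E115 (2.08% to 2.64%). Their list was not called over the span (18 hosts tested, 3 slopes above 0, 0 called, 0 adjusted over the list alone; limma's camera, adjusted p = 0.647). Its abundant members included HDAC2, with a slope of -5.80 (SE 2.21), NCOR1 (-1.99, SE 1.33) and CHD2 (-2.07, SE 1.10). The list of cell cycle, centrosome and mitosis hosts made up 3.49% at both E23 and E42, between 3.16% and 3.42% from E60 to E100, and 2.52% in the E115 library alone, over 37 hosts; without the CSPP1 circRNA it was 2.72% at E23 and 1.34% at E115. None of its 10 tested slopes was above 0 and none was called over all hosts, but their median of -1.50 was near the -1.48 of all hosts, and the lists of RNA binding and splicing, TGF-beta and BMP signalling, and cortex and hippocampus had 0 slopes above 0 as well. These signs hold for scaling by library totals. With TMM factors the median slopes were -0.34 (cell cycle), -0.04 (RNA binding and splicing), 0.42 (TGF-beta and BMP signalling) and -0.83 (cortex and hippocampus), against -0.17 over all hosts. Adjusted over the cell cycle list alone, 2 were called, BUB1B of the spindle checkpoint (-8.20, SE 1.96, edgeR adjusted p = 0.00857) and the DNA topoisomerase TOP2A (-5.53, SE 1.62, adjusted p = 0.0205). They had only 35 and 32 reads over the series, so the size of these slopes is uncertain. Over all hosts their edgeR adjusted p was 0.124 and 0.244. The trend includes the E23 forebrain, so tissue may enter these slopes as well as day. The list as a whole was not called (limma's camera, adjusted p = 0.186). The lists of RNA binding and splicing (10 hosts, PAIP1 and LARP4B the most abundant), axon guidance and neuronal migration (9 hosts, RELN and EPHA3), Wnt signalling (8 hosts, NFATC3 and LRP6), TGF-beta and BMP signalling (5 hosts, SMAD4 and BMPR2), conserved circRNA hosts (14 hosts, CSPP1 and HDAC2) and cortex and hippocampus (3 hosts, CAMK2A among them) were not called either. Their adjusted p from limma's camera lay between 0.611 and 0.976, and none of their members was called over all hosts or adjusted over the list alone. Part of the conserved list was known from the study of these samples, so counts over it are not independent evidence. The cortex and hippocampus list had a median slope of -2.10, below that of all hosts, although camera ranked it upward. circRNAs from markers of vascular, blood, microglial, meningeal and choroid plexus cells stayed between 0.0556 and 0.412 RPM in the cortex series.

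**Figure D3:**
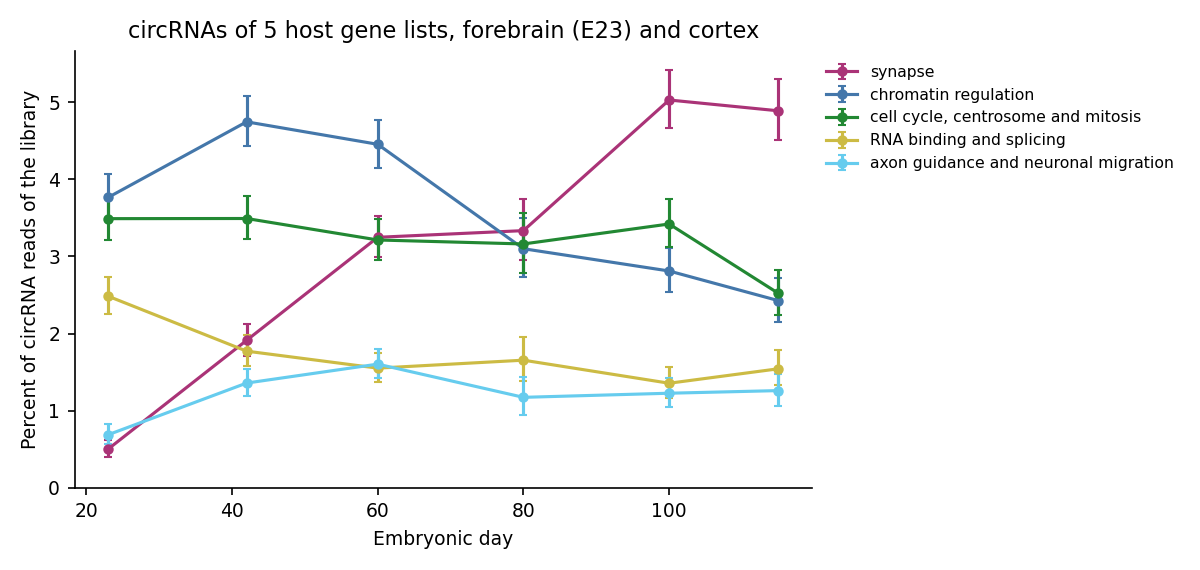
Share of circRNA reads (percent) from the hosts of 5 gene lists in the E23 forebrain and the cortex (points, 1 library each, with 95% exact binomial intervals), against embryonic day. The synapse share goes from 0.503% at E23 to 5.03% at E100, and the chromatin regulation share from 4.74% at E42 to 2.43% at E115, or from 3.01% to 2.35% without the HDAC2 circRNA.

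The comparison of regions asked whether the change from E60 to E115 was shared across the brain, and it was not in these libraries. In the table of 5 regions, the cortex went from 685 RPM of circRNA reads at E60 to 149 at E115 (log2 change -2.20, counting interval -2.24 to -2.16) and the basal ganglia from 183 to 125 (-0.54, interval -0.65 to -0.44). The E115 basal ganglia may lack reads, as they had 0 in every line left out. The cerebellum went from 152 to 386 (1.35, interval 1.27 to 1.43), the brain stem from 39.2 to 133 (1.76, interval 1.63 to 1.89) and the hippocampus from 73.7 to 151 (1.03, interval 0.94 to 1.13). With 3 regions up and 2 down, the mean log2 change was 0.28 (exact sign-flip permutation test over 5 regions, two-sided, p = 0.688). The smallest p this design allows is 0.0625. The mean lay between -0.0915 without the brain stem and 0.90 without the cortex. The numbers of circRNAs with at least 2 reads at E60 and E115 were 2019 and 1200 in cortex, 346 and 230 in basal ganglia, 259 and 976 in cerebellum, 81 and 806 in brain stem, and 318 and 328 in hippocampus (mean log2 change 0.79, exact sign-flip p = 0.438). Such counts move with the number of circRNA reads. With every library drawn down to 518 circRNA reads, the mean log2 change was 0.08 from 2 reads (exact sign-flip p = 0.125; added after the results were seen) and 0.05 from 1 read, which was 0.47 without drawing down. Of 126 circRNAs with at least 50 reads, 15 were higher at E115 than at E60 in cortex, 62 in basal ganglia, 84 in hippocampus, 105 in cerebellum and 111 in brain stem. Log2 ratios used a pseudocount of 0.5 reads, and each of the 126 was counted as higher or lower in every region. This includes any with few or no reads in a region, where library depth can set the direction. The E60 cortex held the highest level of 74 of them (58.7%) and the E115 cerebellum that of 30 (23.8%). The 126 were chosen by reads over all libraries together, of which the E60 cortex had the most (14671). circRNAs high there alone could thus enter, which favours that library in this count. Only 25 of 3134 circRNAs with 2 or more reads somewhere had 2 or more in all 10 libraries. This number could not exceed the 81 detected in the E60 brain stem, so it does not measure how specific circRNAs are to a region or day.

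The circRNA whose host gene the table gives as CDR1 had most reads over the 5 regions. Its level was 18.8 RPM in the E115 cerebellum (16.7 to 21.05), 10.5 in the E60 basal ganglia, 10.3 in the E60 cerebellum and 6.55 in the E60 hippocampus, against 3.04 in the E60 cortex and 2.22 in the E115 cortex. The RIMS2 circRNA stood at 10.5 RPM in the E115 cerebellum (8.96 to 12.2) against 2.92 at E60, and at 10.04 in the E60 cortex. The HDAC2 circRNA was highest in the E60 cortex, with 14.5 RPM and 311 of its 401 reads there and at most 1.40 RPM in the other 9 libraries of this table. The CSPP1 circRNA and that of the co-chaperone gene PTGES3 (chromosome 5, 23683162–23684128) were also highest in the E60 cortex, at 10.6 and 8.22 RPM, as were both TLK1 circRNAs. The circRNA of RELN, the secreted glycoprotein reelin that guides migrating neurons (chromosome 9, 114262312–114333183), was highest in cerebellum, at 2.53 RPM at E60 (1.65 to 3.70) and 4.90 at E115 (3.87 to 6.13). The other circRNAs among the 10 most abundant, from ENSSSCG00000026340, CDK13 and ENSSSCG00000025844, had their highest values in the E115 cortex (3.76), the E60 cortex (4.34) and the E115 cortex (2.43).

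**Figure D4:**
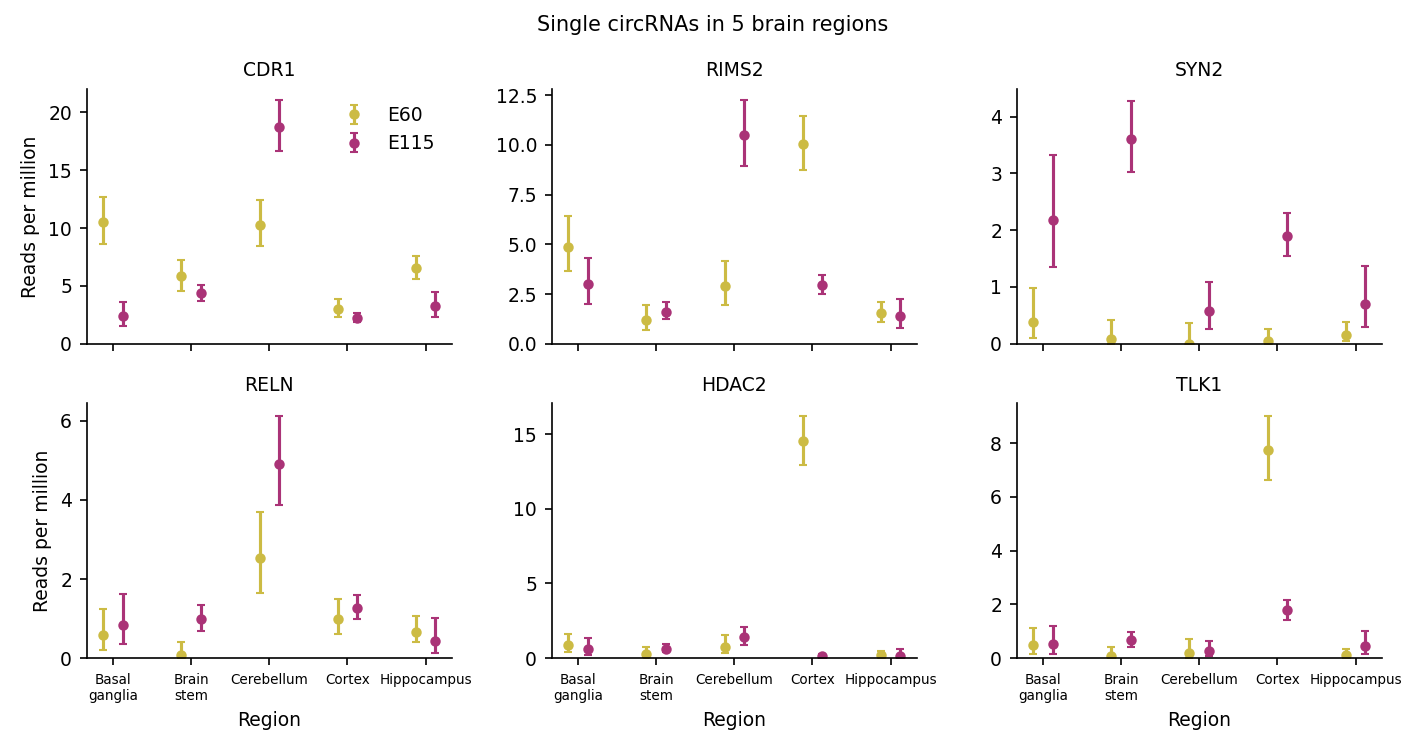
Level in RPM of 6 circRNAs, named by the host gene the table gives, in 5 brain regions at E60 and E115 (points, 1 library each, with 95% exact Poisson intervals). The circRNA assigned to CDR1 and that of RIMS2 stand at 18.8 and 10.5 in the E115 cerebellum, SYN2 is higher at E115 in each of the 5 regions, and HDAC2 stands at 14.5 in the E60 cortex. The TLK1 panel shows the circRNA starting at 86639052.

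The day effect was tested on 387 circRNAs with edgeR, with region as a block so that the 5 regions took the place of replicates. No circRNA passed an adjusted p of 0.05, 4 had an unadjusted p under 0.05, limma called 0 and DESeq2 called 1. The circRNA nearest the threshold was that of SYN2 (log2 change 3.86, SE 1.10, edgeR adjusted p = 0.184). It had more reads at E115 than at E60 in each of the 5 regions, namely 4 and 21 in basal ganglia, 1 and 136 in brain stem, 0 and 9 in cerebellum, 1 and 102 in cortex, and 4 and 8 in hippocampus. It was the circRNA called by DESeq2 (adjusted p = 0.00436) and by edgeR without the cortex libraries (adjusted p = 0.0347). With TMM factors edgeR called SYN2 (log2 change 3.90, adjusted p = 0.000662) and the circRNA of ENSSSCG00000021356 (chromosome 6, 868499–868923; log2 change -4.78, adjusted p = 0.00615), whose 33 reads include 32 at E60. This last name was chosen after its values were seen.

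Few differences between regions were called. The F test of the region terms called 0 of 387 circRNAs (edgeR, 19 with an unadjusted p under 0.05, DESeq2 and limma also 0). Without the E115 cortex some were called, but the cortex is then the E60 library alone, which has the highest total. Cortex against the mean of the other 4 regions called 2 circRNAs, both higher in cortex. They were a circRNA of MORC3, a nuclear ATPase (chromosome 13, 210039530–210045037; log2 difference 4.83, SE 1.21, edgeR adjusted p = 0.0197), with 125 reads in the E60 cortex and 31 in the E115 cortex, and the TLK1 circRNA from 86639052 to 86671532 (log2 difference 4.09, SE 1.05, adjusted p = 0.0197). In this contrast, 74 circRNAs had an unadjusted p under 0.05, DESeq2 called 5 (adding HDAC2, ENSSSCG00000014268 and the TLK1 circRNA from 86622619) and limma 19, all higher in cortex, and without a filter on low counts edgeR called 0. With TMM factors edgeR called the same 2, with smaller log2 differences of 3.42 (MORC3) and 2.90 (TLK1). Scaling by library totals keeps the high total of the E60 cortex in these differences. With at least 50 reads 4 were called. The count was 3 without the E115 cerebellum, 2 without the E115 brain stem, and 0 when any other library of the other 4 regions was left out. Without the E60 cortex neither circRNA was called again, and without the E115 cortex the count rose. Either way the contrast then rests on a single cortex library. The rise thus describes the E60 cortex, with the highest total, and not a cortex difference at both days. Cerebellum against the other regions called 0 (edgeR, 23 with an unadjusted p under 0.05; DESeq2 and limma 0), and 9, all higher in cerebellum, without the E60 cortex. RELN was not called in this contrast (log2 difference 2.36, SE 0.94, edgeR adjusted p = 0.605). Basal ganglia, brain stem and hippocampus each gave 0 calls with edgeR (3 with an unadjusted p under 0.05 each), DESeq2 and limma.

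Gene lists were described in the regions by level and by share of circRNA reads, and differences between regions in these were not tested. circRNAs of synapse hosts went from 5.93 to 30.1 RPM in cerebellum and from 27.5 to 11.2 in cortex between E60 and E115, but as a share of circRNA reads they rose in both, from 3.91% to 7.81% and from 4.01% to 7.53%. The share went from 7.14% to 7.96% in brain stem, from 6.87% to 8.24% in basal ganglia and from 4.47% to 4.29% in hippocampus, with overlapping counting intervals in each. circRNAs of chromatin regulators were at 33.7 RPM in the E60 cortex and at most 12.6 in any other library, but their share was 4.91% there (4.57% to 5.28%) and 4.49% in the E60 cerebellum (3.51% to 5.64%), and without the HDAC2 circRNA 2.79% and 3.97%. circRNAs of the cerebellum list, mostly RELN, reached 6.05 RPM in the E115 cerebellum and 2.53 in the E60 cerebellum, against at most 1.28 elsewhere (1.57% and 1.67% of circRNA reads, against at most 0.915%). Those of the cortex and hippocampus list, CAMK2A among them, were at 3.41 RPM in the E60 cortex and at most 0.414 elsewhere (0.498% of circRNA reads, next to 0.330% in the E115 basal ganglia, from 4 reads, with overlapping intervals). For the day effect, axon guidance and neuronal migration hosts were called lower at E115 (7 hosts, 1 of 7 changes above 0, median -2.002 against 0.14 over all 315 hosts; limma's camera with preset correlation, adjusted p = 0.00929). With TMM factors the median was -1.14 against 0.24 over all hosts (limma's camera, adjusted p = 0.0337). With an estimated correlation this call was lost (adjusted p = 0.885), and on all lines, an alternative chosen after the results were seen, it was lost too while synapse hosts were called higher (limma's camera, adjusted p = 0.0176). Among the lines used here none of the 7 circRNAs was called, over all hosts or adjusted over the list alone, and the list was not called among circRNAs with at least 50 reads. Its members include EPHA3 (log2 change -3.51, SE 2.26), EFNB2 (-3.48, SE 2.32) and RELN (0.81, SE 0.92). The E60 cortex held 34 of the 37 EPHA3 reads and 24 of the 27 EFNB2 reads. As a share of circRNA reads the whole list went from 1.76% to 1.77% in cortex, 2.63% to 2.51% in cerebellum, 0.965% to 1.78% in brain stem, 1.26% to 0.824% in basal ganglia and 2.24% to 0.638% in hippocampus, so a fall in every region was not seen. Synapse hosts were not called (7 hosts, 5 above 0, median 0.75; limma's camera, adjusted p = 0.0933), with SYN2 called when adjusted over the list alone (edgeR, adjusted p = 0.00365). Besides on all lines, they were called when all circRNAs of each host entered. With an estimated correlation, on the lines used here, their adjusted p from limma's camera was 0.885. The other 6 lists tested (chromatin regulation, RNA binding and splicing, cell cycle, Wnt signalling, TGF-beta and BMP signalling, conserved circRNA hosts) had adjusted p from limma's camera between 0.393 and 0.866, and no member was called. Abundant members included HDAC2, ELAVL2 and XRN1, CSPP1 and CDK13, TNIK and AXIN2, SMAD4 and BMPR2, and CDR1 and RIMS2 in turn.

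Some genes gave many circRNAs. 45.6% of 2319 host names in the cortex table and 43.2% of 1886 in the regions table had at least 2. Of those in the cortex table, 26 had 10 or more, among them the chromatin remodeller CHD2 with 20, OMG with 16, the channel kinase TRPM7 with 14, and TBC1D32 with 13. TLK1 had 11 and 1742 reads in all, MORC3 11, and RIMS1, CSPP1 and ENSSSCG00000020975 had 10 each. 1 circRNA supplied 93.0% of the CSPP1 reads and 14.8% of the TBC1D32 reads. Of those in the regions table, 14 had 10 or more, among them KIFAP3 with 14, MYCBP2 with 12 and RIMS1 with 11. The name U6 had 35 on several chromosomes, and it belongs to a small nuclear RNA gene family with many copies, so it names no single locus. Host names come from overlap in the deposited table, and OMG is a short gene that lies inside a larger gene in mammals, so the spliced gene was not established from such a name.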

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

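The tests of library depth, of exchanged day names and of other assignments of days, and both tests of column headings, were chosen only after the results were seen.

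The change in circRNA level (RPM) from E60 to E115 went in opposite directions in different regions, which marks it for a closer look. The log2 change was -0.54 in basal ganglia, 1.76 in brain stem, 1.35 in cerebellum, -2.20 in cortex and 1.03 in hippocampus. The difference between regions was not tested, since each value comes from a pair of single libraries. Depth alone is argued against, because cortex and brain stem were both sequenced deeper at E115 and their log2 changes lay 3.96 apart with separate counting intervals. So are a few dominant circRNAs, because 5 of 5 regions kept their direction without the 10 circRNAs with most reads. If regions share part of their change, which was not tested, exchanged day names would make changes of single circRNAs run against the cortex. The E60 brain stem had 518 circRNA reads, so its changes rest on few. The rank correlation with the cortex across circRNAs, which are not independent replicates, was 0.230 in brain stem (adjusted permutation p = 0.038). In hippocampus it was 0.395 (adjusted permutation p = 0.0004, raw p the smallest that the permutations drawn can give). In cerebellum it was 0.0586 (adjusted permutation p = 0.531), which leaves an exchange open there. The share of synapse hosts ran as the names say, from 3.91% at E60 to 7.81% at E115 in cerebellum beside 4.01% to 7.53% in cortex, and so did SYN2 with 0 and 9 reads, but in hippocampus that share was 4.47% and 4.29%, so its direction does not settle the names. A difference between the regions in their time course remains an untested biological explanation.

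There are 16 ways of swapping the days within regions, too few for a share under 0.05. The real days gave 0 calls and the highest of the other assignments gave 0. With an unadjusted edgeR p under 0.05 there were 4 circRNAs for the real days, 40 with brain stem and cerebellum swapped, 48 with cortex swapped and 95 with brain stem, cerebellum and hippocampus swapped. The last makes the totals of all 5 regions fall together, so it restates their opposite changes.

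The highest cortex level at E42 and E60 was weighed as well. Depth alone is argued against by the 2.11-fold ratio of E42 to E80 at nearly equal depth. A part played by depth stays open, since E60 was the shallowest library of the series, at 21.4 M reads. The deepest, E23, E100 and E115, had the lowest levels. A few dominant circRNAs are argued against by the 3.11-fold ratio of E60 to E23, E80, E100 and E115 together without the 10 circRNAs with most reads. A common difference in circRNA yield between library preparations cannot be told apart from a change in the tissue. The ratios of single circRNAs from E60 to E115 spread 8.63 times as widely as counting error gives, but single libraries differ by more than counting error in any case, so this decides nothing and a common factor stays open. A stage-dependent level is the untested biological explanation.

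Host FPKM values headed cortex in the regions table differed from those of the cortex table. The rank correlation across hosts was 0.787 at E60 and 0.709 at E115, which argues against a mere rescaling. Columns headed hippocampus were nearest to the values of the cortex table, which are headed by day only and were taken as cortex, at 0.953 and 0.962. Exchanged headings in the regions table are thus a candidate explanation, as are hippocampus values placed in the cortex table. Neither alone would change the order of genes, so the mismatch that remains is unexplained. Backsplice reads of the cortex were the same in both tables wherever lines added up, and host FPKM values of the regions table were not used elsewhere.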

How the results depend on the processing

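TMM factors without E23, all lines, drawing down with detection from 2 reads, the synapse list without SYN2 and the alternatives for host FPKM were chosen only after the results were seen. Over 15 results, 139 of 177 alternatives kept the direction and the side of the threshold or, for a count, gave a value within 1.5 times, not mainly in the other direction, with the same gene lists called. Basal ganglia, brain stem and hippocampus against the other regions gave 0 calls under all 17 alternatives each. These are among the 139 but say nothing about stability, since their counts at an unadjusted p under 0.05, 3 each, ranged from 0 to 13, 26 and 15.

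The day effect went from 0 calls to 2 with TMM factors, 2 with DESeq2 size factors, 1 with the DESeq2 test and 1 without cortex (0 to 1 over left-out regions). The region effect had calls only without the E115 cortex, which leaves the E60 cortex, with the highest total, as the single cortex library. The cerebellum contrast ranged from 0 to 9 over left-out libraries. The cortex contrast went from 2 to 0 without a filter, 4 with at least 50 reads, 5 with DESeq2 and 19 with limma, and ranged from 0 to 89 over left-out libraries. The cortex trend went from 3 to 41 with TMM factors (27 up, 14 down), 42 with DESeq2 size factors (28 up, 14 down), 20 with the DESeq2 test, 0 with limma, 1 with log2 of the day and 42 with TMM factors without E23 (30 up, 12 down), and ranged from 0 to 178 over left-out libraries. Scaling by totals keeps the shift of most circRNAs with day, which TMM and DESeq2 factors remove by construction. For the other changes the cause was not tested.

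Of the gene lists, the day effect went from 1 call to 0 with an estimated correlation, 2 with all circRNAs of each host, 0 with at least 50 reads and, on all lines, 1 that was the synapse list (up) in place of the axon guidance list (down), and the cortex trend from 1 to 0 with an estimated correlation. The mean log2 change in circRNA level (RPM) between E60 and E115 ranged from -0.0915 without the brain stem, a reversed sign, to 0.90 without the cortex, around a value of 0.28 that passed no test. With libraries drawn down to 8098 circRNA reads, the number of circRNAs detected from 1 read in the cortex series had rho -0.83 with day (exact permutation p = 0.0583) and r -0.84 (exact permutation p = 0.0486, not adjusted), against rho -0.66 without drawing down. From 2 reads, drawing down gave rho -0.49 (exact permutation p = 0.356) and r -0.59.

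The E60 brain stem has the fewest circRNA reads, 518 of 13.2 M reads, and the lines left out held 35.9% of its reads. On all lines its log2 change was 1.21. Ratios of circular to linear reads were not analysed here.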

Other observations

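The tests of circRNAs by host gene were not among the results planned at the start. They were chosen before their results were seen, and the alternatives for host FPKM and the shares without CDR1 after.

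Glial and region marker genes contributed few circRNAs. circRNAs of the oligodendrocyte lineage list, nearly all from VCAN, were at 6.67 RPM in the E42 cortex and 0.352 in the E115 cortex. VCAN is also expressed outside that lineage, so these values do not measure oligodendrocytes. In the regions table the list was highest in the E60 cerebellum, at 4.08 RPM. circRNAs of the astrocyte and radial glia list, mostly from the cytokine receptor gene LIFR, lay between 0.263 and 1.05 RPM in the cortex series and reached 1.31 in the E60 cortex and 1.21 in the E115 cerebellum of the regions table. The basal ganglia list, led by ARPP21 and PDE10A, was not highest in the basal ganglia: it stood at 0.191 RPM there at E60 and 0.103 at E115, from 2 reads and 1 read, and at 2.10 in the E60 cortex (0.105%, 0.0824% and 0.307% of circRNA reads, with overlapping intervals). The brain stem list, with NFIB and EBF1, reached at most 0.292 RPM in the regions table and 0.412 in the cortex series. The cerebellum list in the cortex series, nearly all from RELN, was highest at E42 (2.85 RPM). circRNAs of vascular, blood, microglial, meningeal and choroid plexus genes such as FLT1 and TFRC reached at most 0.310 RPM in the regions table and 0.412 in the cortex series.

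Conserved circRNA hosts, CDR1, RIMS2 and CSPP1 among them, gave 23.7% of the circRNA reads of the E60 brain stem and 8.34% of those of the E60 cortex. The circRNA assigned to CDR1 gave 77 of the 123 reads in the E60 brain stem, and without it the shares were 8.88% (6.57% to 11.7%) and 7.90%. Their share was nearly level in cerebellum, 12.3% at E60 and 11.7% at E115, where their RPM rose from 18.7 to 45.3 with all circRNA reads, and went from 15.2% to 9.07% in basal ganglia (9.39% to 7.17% without CDR1, with overlapping intervals). Across circRNAs, the E115 cortex resembled the E115 brain stem (r = 0.722 between log values) more than the E60 cortex (r = 0.230), but the E60 cortex stood apart from all 9 others (r from 0.147 to 0.383). The 126 circRNAs compared were chosen by their reads over all libraries together, and the E60 cortex had the most reads, 14671. circRNAs high there alone could thus enter, which can lower its r with the others. Among libraries other than cortex the median r was 0.663 within a day and 0.625 within a region. circRNAs are not independent replicates, and these values carry no test.

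Whether a circRNA followed the RNA level of its host gene over the cortex stages was tested with circRNAs of at least 50 reads. The median rank correlation between circRNA level and host FPKM over the 6 stages was 0.619 for 266 circRNAs from 228 hosts, above the highest of 1000 medians with hosts shuffled (0.371). Host FPKM is a level of RNA and does not measure transcription. In total RNA it may also count reads from the exons of the circRNA itself, which could raise the correlation and were not separated here. The cortex host FPKM values of E60 and E115 differ between the tables. Those of the cortex table, used here, are headed by day only and were taken as cortex. They would be hippocampus values if the error lies in that table. The median was 0.771 with at least 100 reads, 0.543 with at least 20 reads and 0.731 as Pearson's r. circRNAs of the same host also shared their profile, with a median rank correlation of 0.771 over 49 pairs from 28 hosts, above the highest shuffled median (0.714). The RNA level of the host may thus account for part of a circRNA's course. It may not account for all of it: the median log2 ratio of circRNA level to host FPKM, each relative to its own mean over the stages, was -0.24 at E23, 0.37 at E42, 0.83 at E60, 0.15 at E80, -0.31 at E100 and -0.43 at E115. The ratio was thus highest at E60, where total circRNA was highest too, and a common yield of the E60 library preparation would give the same.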
